A study of Homo sapiens with 18 samples.

How the data were processed

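RNA sequencing was analysed for 18 libraries from the human cell lines JEKO1 and MAVER, both from mantle cell lymphoma, a B cell cancer in which most cases overexpress cyclin D1. The sample titles place the libraries in 6 groups of 3 replicates lettered A, B and C: JEKO1 with DMSO or IB, and MAVER with DMSO, IB, KPT or PU, all at 6 h. DMSO is the solvent control. IB was read as ibrutinib, an inhibitor of the B cell receptor kinase BTK, at 0.4 µM, and KPT as selinexor, an inhibitor of the nuclear exporter XPO1, at 1.5 µM, since these are the inhibitors that the series description names. PU is not defined in the sources used here and is given as written. The labels call the replicates biological; how the cultures were separated is not given, so p-values measure the spread between these libraries.

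Per the labels' protocols, total RNA was made into stranded TruSeq libraries and sequenced as single-end reads of 50 bp on an Illumina HiSeq instrument at a stated depth of 30 M reads. Per the same protocols, STAR aligned the reads to the transcriptome, Cufflinks estimated abundance and DESeq2 tested drug against DMSO. The submitters' processing notes add FastQC and the genome build hg19, without versions. The read counter, its strand setting and the gene annotation are not given in the sources used here. No genome coordinates are printed, since the reference at hand was of another build.

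The values deposited by the authors are normalized counts, a signal per gene that is never negative: reads per gene divided by 1 factor per library, in 2 tables, 1 per cell line. Every value was a whole multiple of the smallest positive value of its library, within 0.01 read for 100% of values, so whole reads could be recovered. The recovered totals are 5374226 to 17040599 reads per library. The tables were normalized separately, so levels of the lines are not compared and each test was run within a table. Each table lists 25369 genes, of which 28 carry names altered to dates; those that passed the filter (18 in JEKO1 and 17 in MAVER) stayed in the tests and are not named. Mitochondrially encoded genes were not analysed here. In the list tests, TIGAR was matched as C12orf5 and JCHAIN as IGJ.

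Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with a mean-variance trend) on log2(normalized count + 1), for genes with a mean of at least 10 over the libraries of the table. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and "rose" or "fell" is used only of those. Fold changes are on the log2(value + 1) scale, which understates changes of genes with few reads. The 4 MAVER groups were fitted together and share 1 estimate of the spread. The difference of the IB effect between lines was tested on the 12 JEKO1 and MAVER libraries with IB or DMSO, as the JEKO1 effect minus the MAVER effect, each taken within its own table. These tests, 29 gene lists, the alternatives and the rule for named genes were fixed before the data were examined.

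Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, for lists with at least 5 measured members, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test was repeated with a correlation estimated from the libraries, and a call that was lost is given with that adjusted p. Member counts are given over all genes tested and adjusted over the list alone. Named genes are, per comparison, the 8 with the largest rise and the 8 with the largest fall among called genes with a mean of at least 50 and no overlap between libraries of the compared groups, the 4 members of each list with the smallest p, and BTK, XPO1 and NFKBIA. Some genes that this rule takes are not reported here. Genes with near-identical copies, such as HSPA1B, HLA-DRB1, the histone genes and the ribosomal protein genes with their pseudogenes, share reads in ways the counting may split, so their values are uncertain. Antisense and overlapping genes are likewise uncertain, because the strand setting of the counting is not given.

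Replicates were compared before use. The chi-square statistic of recovered reads per degree of freedom was 1.39 to 4.92 over pairs of the same group, so no pair agreed within sampling noise and no library was counted as a copy. The lowest correlation within groups, across genes on the log2 scale, was 0.9925 in JEKO1 and 0.991 in MAVER. The highest between groups was 0.9754 in JEKO1 and 0.9878 in MAVER.

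The alternatives were other pseudocounts and filters, rescaling to equal totals or upper quartiles, eBayes without trend, the replicate letter as a block, fits of the compared groups alone, leaving out each replicate, and edgeR 4.0.16 (quasi-likelihood test with TMM) and DESeq2 1.42.0 on the recovered reads. Chosen after seeing the data were the KPT results without libraries rich in RNA45S5, thinning of reads to the shallowest MAVER library, the difference between lines with the JEKO1 labels exchanged, and the left-out replicates and upper-quartile scaling for the gene list tests. Comparisons that share control libraries were set beside 20 simulations of unchanged groups.

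The limma test was tested on simulated reads drawn from the real means and depths. For the IB comparison in JEKO1 (11540 genes) it recovered 49% of genes changed 1.25-fold, 92% at 1.5-fold, 96% at 2-fold and 100% at 3-fold, with 5 false calls (2.9% of calls). For IB in MAVER (11052 genes) these shares were 66%, 78%, 96% and 100%, with 11 false calls (6.1%). For KPT in MAVER (11031 genes) they were 55.1%, 89.8%, 95.8% and 100%, with 10 false calls (5.6%). For the difference between lines (10629 genes) they were 44%, 82%, 86% and 92%, with 13 false calls (7.9%), so the share of false calls was above the nominal 5% in 3 of these 4 simulations. The list test, for IB in JEKO1, IB in MAVER and KPT, called a list shifted 1.3-fold and called 0 of 20 unshifted lists in each. Genes were drawn independently there, so false calls for lists whose members vary together were not tested. In the real data the estimated correlation was, for example, 0.369 for glycolysis genes with IB in JEKO1.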

Results

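Transcript levels were measured in 18 libraries of the mantle cell lymphoma lines JEKO1 and MAVER after 6 h with solvent or drug, with n = 3 libraries in each of 6 groups. The series title sets ibrutinib-sensitive beside ibrutinib-resistant tumour cells and concerns XPO1 inhibition and the NF-kB inhibitor IkB. Which line is which is not given in the sources used here. Recovered depth was 9023575 to 11695852 reads in JEKO1 DMSO libraries and 8764566 to 12627963 in JEKO1 IB libraries. In MAVER it was 9897029 to 12085782 with DMSO and 8415254 to 9810362 with IB. It was 5374226 to 7924550 with KPT and 8035123 to 17040599 with PU. Libraries differed in their content of RNA45S5, the ribosomal RNA precursor, which has no poly(A) tail. RNA45S5 stood at 53819 normalized counts in KPT replicate A, 66933 in KPT replicate C and 65331 in JEKO1 DMSO replicate C. It was 32274 in PU replicate A, 9092 in KPT replicate B and 7919 to 25147 in the other libraries.

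**Figure D1:**
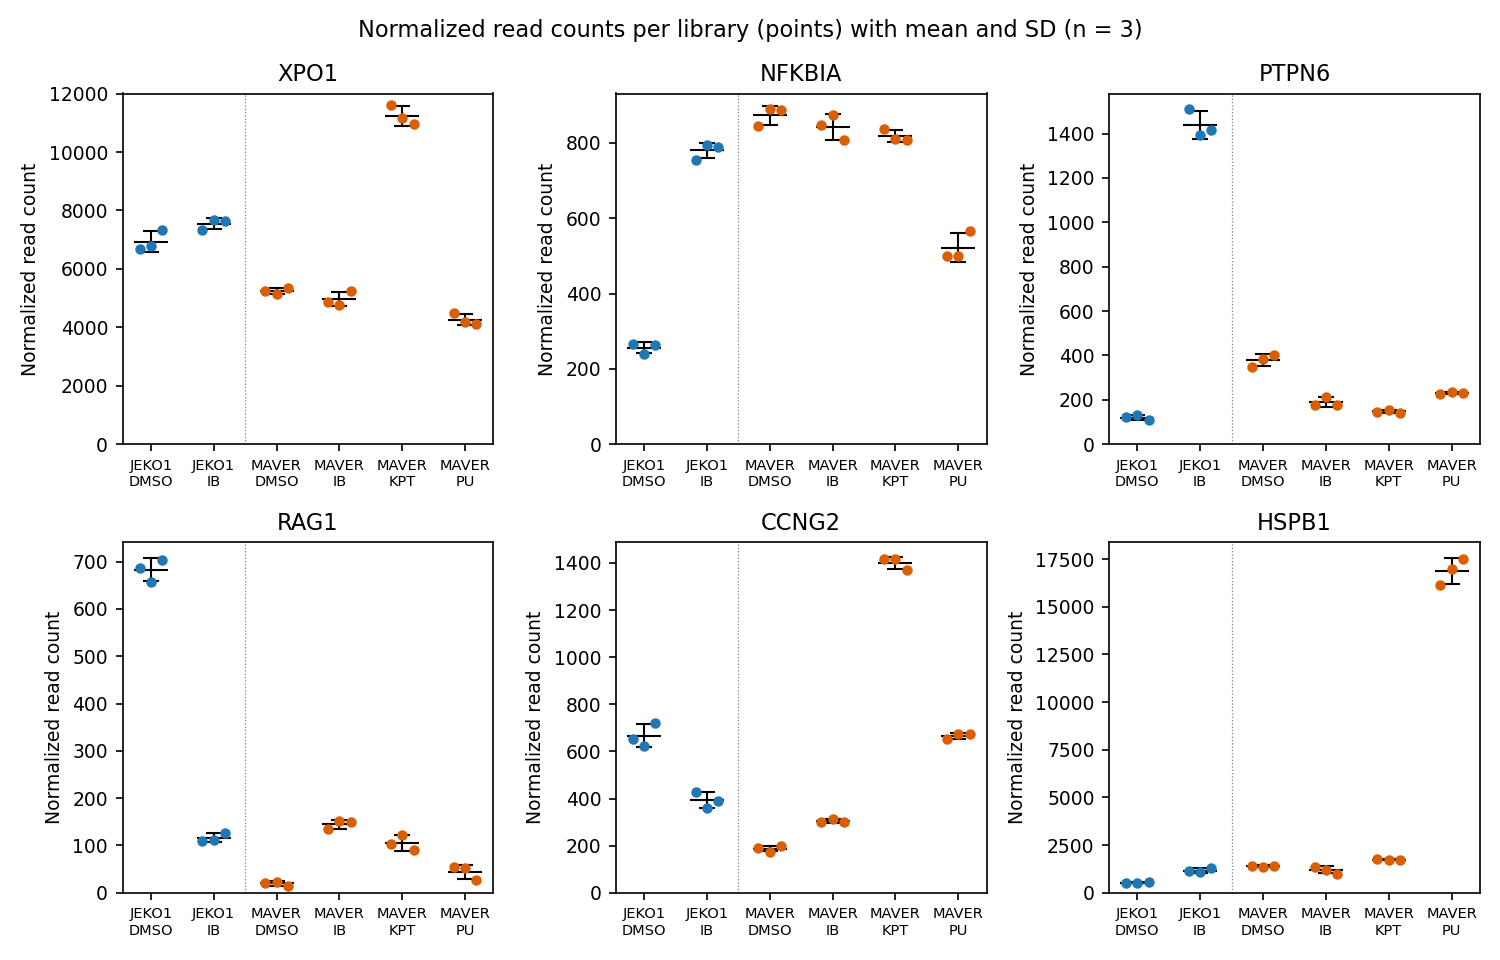
Normalized read counts of XPO1, NFKBIA, PTPN6, RAG1, CCNG2 and HSPB1 in each library (points), with the group mean and SD (n = 3); the dotted line parts the separately normalized JEKO1 and MAVER tables. XPO1 is highest with KPT (mean 11244), HSPB1 with PU (mean 16877), and RAG1 is lower in the JEKO1 libraries labelled IB and higher with IB in MAVER.

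The first comparison set the JEKO1 libraries labelled IB against those labelled DMSO. An exchange of these labels could not be told apart from an opposite response of the lines, as weighed below. Every direction given for JEKO1 holds for the labels as given and may be inverted. In the libraries labelled IB, targets of NF-kB and genes of the immediate response to antigen receptor signals were higher than in the DMSO libraries. NFKBIA, which encodes IkB alpha, stood at 780 ± 21.2 normalized counts (SD, n = 3) against 257 ± 14.2 with DMSO, a log2 fold change of 1.60 ± 0.07 (SE; limma adjusted p = 3.48e-13). CD83, an activation marker of B cells, rose from 163 ± 12.5 to 1078 ± 77.6, and ICAM1, an adhesion molecule, from 84.9 ± 11.1 to 577 ± 20 (SD, n = 3). NFKB2 rose by 2.10 ± 0.08 and NFKBIE, another NF-kB inhibitor, by 1.85 ± 0.06 (log2 fold change ± SE). Of 34 measured NF-kB targets, 30 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 6.79e-22, and 0.0123 with an estimated correlation).

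Among 29 immediate early genes, 23 rose and 2 fell (24 and 2 adjusted over the list alone; camera adjusted p = 3.68e-11). EGR1, a transcription factor induced within minutes of receptor signals, rose from 17.7 ± 3.12 to 211 ± 15.8 normalized counts (SD, n = 3). JUNB rose by 1.71 ± 0.08 and the nuclear receptor NR4A1 by 1.82 ± 0.11 (log2 fold change ± SE). MYC was one of the genes that fell, from 11754 ± 121 to 7369 ± 354. All 7 measured ERK feedback genes rose, also when adjusted over the list alone (camera adjusted p = 6.66e-06, but adjusted p = 0.0523 with an estimated correlation). DUSP5 rose by 3.33 ± 0.21 and SPRED2 by 2.48 ± 0.29 (log2 fold change ± SE).

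Components of the B cell receptor pathway moved both ways, with 15 of 31 up and 9 down, the same counts when adjusted over the list alone. Its camera test gave an upward call (adjusted p = 0.0311, but adjusted p = 0.328 with an estimated correlation). PTPN6, the phosphatase SHP-1, rose from 120 ± 11.6 to 1440 ± 62.4 normalized counts (SD, n = 3). RAC2 rose by 1.52 ± 0.08 (log2 fold change ± SE). BTK itself rose from 2281 ± 26.7 to 2816 ± 82.7 (log2 fold change 0.30 ± 0.04, limma adjusted p = 8.42e-06). XPO1 differed by 0.12 ± 0.04 (limma adjusted p = 0.0208). That call was lost without DMSO replicate A (adjusted p = 0.127), DMSO replicate B (0.0941), IB replicate B (0.0916) or IB replicate C (0.0515), and without the variance trend (0.146).

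Ribosomal protein transcripts were lower, with 44 of 50 down and 0 up (47 down adjusted over the list alone; camera adjusted p = 1.44e-14). RPL22 fell by 0.58 on the log2 scale (SE 0.05). JEKO1 DMSO replicate C, rich in RNA45S5 at 65331 normalized counts, belongs to the higher side of this difference. The list stayed called when that library was left out, a setting chosen after seeing the data. Genes of the G1/S transition were higher, with 25 of 40 up and 2 down (27 and 2 adjusted over the list alone; camera adjusted p = 2.39e-06). The thymidylate synthase TYMS rose by 0.41 ± 0.04 (log2 fold change ± SE). Mitotic genes were lower, with 26 of 40 down and 2 up, the same adjusted over the list alone (camera adjusted p = 4.53e-06, but adjusted p = 0.281 with an estimated correlation). The phosphatase CDC25B fell by 0.42 on the log2 scale (SE 0.04). The calls for NF-kB targets, immediate early genes, G1/S genes and ribosomal proteins held with an estimated correlation (adjusted p = 0.0123, 0.0223, 0.0365 and 0.0453).

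Heat shock chaperones rose in 21 of 28 cases and fell in 2 (22 and 2 adjusted over the list alone; camera adjusted p = 2.51e-08, but adjusted p = 0.0806 with an estimated correlation). HSPB1 rose from 534 ± 10.3 to 1167 ± 114 normalized counts and HSP90AA1 from 18276 ± 810 to 30351 ± 1177 (SD, n = 3). Interferon-stimulated genes rose in 18 of 29 cases and fell in 5 (19 and 5 adjusted over the list alone; camera adjusted p = 0.00104, but adjusted p = 0.0596 with an estimated correlation). MX1 rose by 1.58 ± 0.10 and BST2 by 1.49 ± 0.10 (log2 fold change ± SE). Proteasome subunits rose in 26 of 32 cases and fell in 0 (30 and 0 adjusted over the list alone; camera adjusted p = 9.72e-09, but adjusted p = 0.141 with an estimated correlation).

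The genes with the largest changes included the signal-inhibitory receptor SIRPA (10 ± 4.99 to 146 ± 7.3 normalized counts), the ligand WNT10A (7.48 ± 1.63 to 118 ± 10.3) and the semaphorin SEMA7A (10.3 ± 2.35 to 124 ± 6.52), all higher in the libraries labelled IB (SD, n = 3). The recombinase gene RAG1 fell from 683 ± 24.4 to 116 ± 9.42 and the taste receptor gene TAS1R3 from 336 ± 46 to 42.9 ± 9.09. FBP1, an enzyme of gluconeogenesis, fell from 216 ± 22 to 50.6 ± 6.53. In all, 2538 genes rose and 2341 fell of 11609 tested (limma, adjusted p under 0.05), 344 and 192 of them by at least 2-fold. The compared libraries did not overlap for 50.2% of genes, where chance gives 10%.

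In MAVER the same drug label was compared with DMSO. Here RAG1 rose from 19.6 ± 4.51 to 145 ± 9.63 normalized counts (SD, n = 3). TMCC2, a membrane protein gene, rose from 107 ± 13.9 to 507 ± 9.13 and FBP1 from 75.1 ± 7.2 to 236 ± 8.61. TP53INP1, a p53-inducible regulator of cell death and autophagy, rose from 748 ± 8.78 to 2240 ± 182 and the growth factor gene BMP7 from 77.9 ± 10 to 231 ± 11.9. MAP2, a microtubule-associated protein, fell from 244 ± 30.3 to 55.3 ± 8.05. MPEG1, which encodes the pore-forming protein perforin-2, fell from 788 ± 30.6 to 272 ± 25.1, WNT10A from 219 ± 28.2 to 72.4 ± 3.48, and the lectin CLEC17A from 195 ± 6.31 to 59.4 ± 8.27. NFKBIA stood at 842 ± 33.6 with IB and 873 ± 25.1 with DMSO (log2 fold change -0.05 ± 0.06, limma adjusted p = 0.61). XPO1 stood at 4965 ± 250 and 5232 ± 99.2 (-0.08 ± 0.04, adjusted p = 0.214). BTK was lower by a small margin (-0.14 ± 0.04, adjusted p = 0.0161). That call was lost without DMSO replicate B (adjusted p = 0.0793), without IB replicate C (0.0851), without the variance trend (0.0596) or with thinned reads (0.0559).

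Chaperones and oxidative stress genes were lower with IB in MAVER. Of 30 heat shock chaperones 20 fell and 0 rose (23 and 0 adjusted over the list alone; camera adjusted p = 1.43e-10), including HSPH1 (-0.45 ± 0.04, log2 fold change ± SE) and HSPA8 (-0.37 ± 0.04). Of 22 NRF2 oxidative stress genes 9 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.000304), including the cystine transporter gene SLC7A11 (-0.76 ± 0.07) and HMOX1 (-0.50 ± 0.06). Both calls held with an estimated correlation (adjusted p = 0.0276 and 0.0341). Of 28 genes of the unfolded protein response of the endoplasmic reticulum 18 fell and 3 rose (19 and 3 adjusted over the list alone; camera adjusted p = 4.92e-06, but adjusted p = 0.0696 with an estimated correlation). CALR and HERPUD1 fell (-0.32 ± 0.04 and -0.37 ± 0.05), while XBP1, a transcription factor of this response, rose (0.39 ± 0.04).

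Of 26 immediate early genes 13 fell and 2 rose (16 and 4 adjusted over the list alone; camera adjusted p = 2.45e-05, but adjusted p = 0.0983 with an estimated correlation). NAB2, RGS2 and NR4A1 fell to 129 ± 8.88, 115 ± 17.1 and 131 ± 8.83 normalized counts from 294 ± 20.1, 237 ± 25.7 and 274 ± 23.1 (SD, n = 3). NF-kB targets moved both ways, with 8 of 31 up and 6 down, also when adjusted over the list alone (camera adjusted p = 0.287). BIRC3 rose by 0.60 ± 0.05 and PIM2 by 0.53 ± 0.05, while JUNB fell by 0.65 on the log2 scale (SE 0.08). Of 29 B cell receptor components 9 rose and 13 fell, also when adjusted over the list alone (camera adjusted p = 0.209). The kinase gene PRKCB rose from 1956 ± 32 to 4097 ± 94.3 and the receptor subunit gene CD79B from 3978 ± 183 to 6173 ± 168.

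Smaller shifts were called for proteasome subunits (12 of 32 down, 0 up; 15 and 0 adjusted over the list alone; camera adjusted p = 2.45e-05, but adjusted p = 0.0983 with an estimated correlation). Mitotic genes rose in 12 of 40 cases and fell in 0 (14 and 0 adjusted over the list alone; camera adjusted p = 5.22e-05, but adjusted p = 0.194 with an estimated correlation). CDC25B rose by 0.63 ± 0.04. Ribosomal proteins rose in 11 of 51 cases and fell in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 0.000609, but adjusted p = 0.241 with an estimated correlation). Of 25 p53 targets 7 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.026, but adjusted p = 0.133 with an estimated correlation). Without IB replicate C the preset correlation gave adjusted p = 0.055. CDKN1A, the cell cycle inhibitor p21, was the gene that fell, from 630 ± 6.3 to 285 ± 28.5 normalized counts (SD, n = 3). Over all genes, 1126 rose and 1071 fell of 11099 tested (limma, adjusted p under 0.05), 83 and 71 by at least 2-fold. Libraries did not overlap for 33.8% of genes, against 10% by chance.

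The IB effect was then set against itself between the lines. PTPN6, WNT10A, MPEG1 and the B cell surface protein CD72 were higher with IB in JEKO1 and lower in MAVER, with differences of log2 fold change (JEKO1 minus MAVER) of 4.56 ± 0.12, 5.40 ± 0.24, 3.79 ± 0.10 and 3.35 ± 0.10 (SE; n = 3 per group). RAG1, TMCC2 and FBP1 went the other way, with differences of -5.39 ± 0.19, -4.18 ± 0.13 and -3.72 ± 0.18. Of 30 B cell and mantle cell lymphoma identity genes the effect was higher in JEKO1 for 12 and lower for 11, also when adjusted over the list alone, with no call for the list (median 0.065, camera downward, adjusted p = 0.981). Among these, SPIB rose in JEKO1 (1.06) and fell in MAVER (-0.84), while BACH2 (-0.91 and 0.80) and POU2AF1 (-0.82 and 0.90) did the reverse. The difference was 1.65 ± 0.08 for NFKBIA (limma adjusted p = 1.19e-14), 0.44 ± 0.06 for BTK (6.1e-07) and 0.20 ± 0.06 for XPO1 (0.00784, and 0.0547 without the variance trend).

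By list, the effect was higher in JEKO1 for 23 of 31 NF-kB targets and lower for 3 (the same adjusted over the list alone; camera adjusted p = 1.1e-13). It was higher for 21 of 25 immediate early genes and lower for 2 (the same adjusted over the list alone; camera adjusted p = 7.65e-10). It was higher for 23 of 28 heat shock chaperones and lower for 0 (23 and 1 adjusted over the list alone; camera adjusted p = 3.63e-10). Of 32 proteasome subunits 28 were higher and 0 lower (29 and 0 adjusted over the list alone; camera adjusted p = 7.65e-10). The effect was also higher for 15 of 22 NRF2 genes and lower for 0 (16 and 0 adjusted over the list alone; camera adjusted p = 1.05e-06). It was lower for 42 of 50 ribosomal proteins and higher for 0 (43 and 0 adjusted over the list alone; camera adjusted p = 1.07e-12). These 6 calls held with an estimated correlation (adjusted p = 0.00481 for NF-kB targets, 0.0373 for proteasome subunits and 0.015 for each of the others). For mitotic genes the effect was lower in JEKO1 for 27 of 40 and higher for 1, also when adjusted over the list alone (camera adjusted p = 3.18e-07, but adjusted p = 0.143 with an estimated correlation).

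The IB effect was higher in JEKO1 for 2301 genes and lower for 2084, of 10591 tested (limma, adjusted p under 0.05). Of 10632 genes tested in each line, 1415 were called in both, and 1260 of these (89%) moved opposite ways and 155 the same way. If the DMSO and IB labels of JEKO1 were exchanged, these numbers would change places, and 2424 genes would differ between the lines. Of the called genes, 647 rose in JEKO1 and fell in MAVER, where independent lists of these sizes would share 231. Another 613 fell in JEKO1 and rose in MAVER (223). Both lines rose for 95 genes (240) and fell for 60 (214). All 70 genes that changed at least 2-fold in both lines moved opposite ways. Across genes, which are not independent replicates, the log2 fold changes of the lines had r = -0.508 and rho = -0.384; the lines share no control library.

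**Figure D2:**
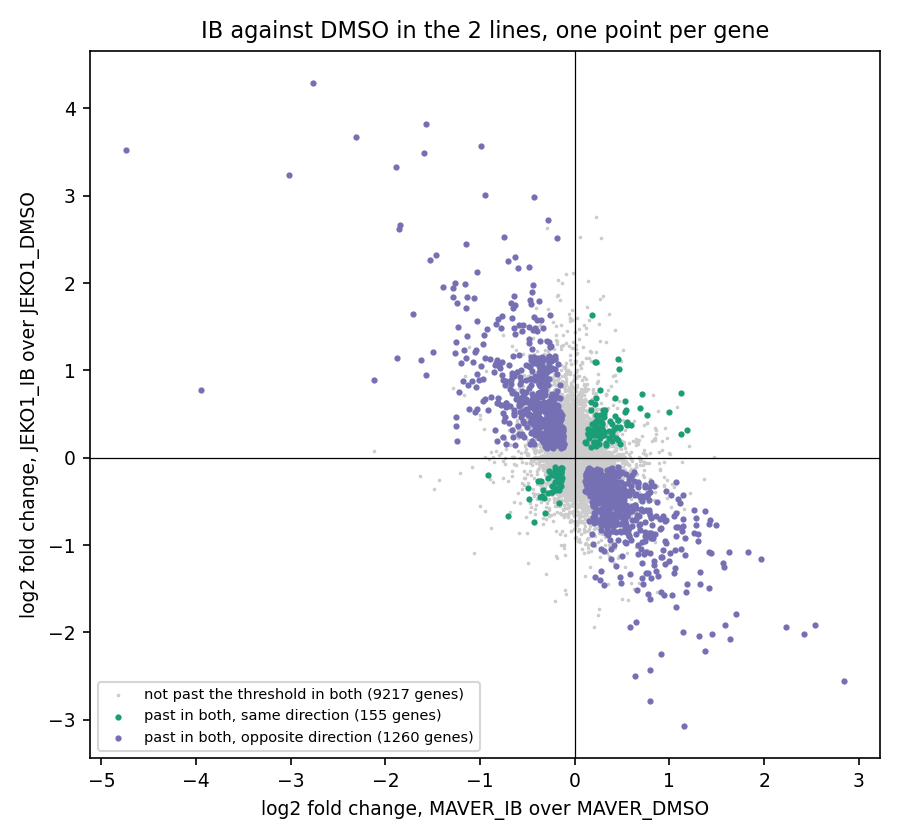
Log2 fold change of IB over DMSO in JEKO1 (vertical axis) against MAVER (horizontal axis), 1 point per gene; purple points passed the test in both lines with opposite signs (1260 genes), green points with the same sign (155 genes), and grey points did not pass in both. The purple points fill the upper left and lower right.

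The next comparison asked which transcripts follow XPO1 inhibition in MAVER. XPO1, the drug's target, rose from 5232 ± 99.2 to 11244 ± 346 normalized counts with KPT (SD, n = 3; log2 fold change 1.10 ± 0.04 SE, limma adjusted p = 8.17e-24). CCNG2, a cyclin that restrains the cell cycle, rose from 188 ± 12 to 1399 ± 27. ARRDC3, an arrestin-domain protein, rose from 487 ± 15 to 3501 ± 58.6, and NDRG1 from 34.8 ± 7.85 to 254 ± 23.6. The ubiquitin ligase component FBXO32 rose from 30.5 ± 4.31 to 206 ± 2.57 and the calpain gene CAPN5 from 14.5 ± 6.57 to 171 ± 15.7. HK2, the hexokinase of the first step of glycolysis, fell from 1119 ± 1.56 to 219 ± 11.6. The cytokine receptor gene IL21R fell from 206 ± 4.89 to 49.3 ± 7.29, and PPARGC1B, a coactivator of mitochondrial genes, from 318 ± 16.4 to 88.4 ± 17.1. NFKBIA stood at 818 ± 17 with KPT (log2 fold change -0.09 ± 0.06, adjusted p = 0.182) and BTK at 2805 ± 40.7 (-0.02 ± 0.04, adjusted p = 0.755).

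Genes of the nuclear transport system were mostly lower: of 33, XPO1 included, 24 fell and 3 rose, XPO1 among the latter (25 and 3 adjusted over the list alone; camera adjusted p = 3.78e-06). The exporter XPO5 fell from 1980 ± 78.3 to 903 ± 8.42 normalized counts (SD, n = 3), the importin KPNA2 from 2462 ± 18.3 to 1364 ± 47.7, and RANGAP1, the activator of the Ran GTPase, from 3461 ± 210 to 2129 ± 130. MYC-linked and ribosome biogenesis genes were lower, with 29 of 39 down and 3 up (30 and 3 adjusted over the list alone; camera adjusted p = 8.12e-10). Among them were the spermidine synthase SRM (-1.08 ± 0.05, log2 fold change ± SE), RRS1 (-1.11 ± 0.05), RRP12 (-1.05 ± 0.06) and the nucleolar protein NOLC1 (-0.82 ± 0.04). Where the text below says ribosome biogenesis genes, this mixed list with its MYC-linked members is meant.

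Ribosomal proteins and interferon-stimulated genes were higher with KPT. Of 51 ribosomal protein genes 49 rose and 0 fell, also when adjusted over the list alone (median log2 fold change 0.34, camera adjusted p = 7.13e-18), such as RPLP0 (0.50 ± 0.04, SE) and RPL13A (0.58 ± 0.05). Of 33 interferon-stimulated genes 19 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 9.93e-06). TRIM22, an antiviral ubiquitin ligase, rose from 820 ± 16.5 to 3080 ± 8.13 normalized counts (SD, n = 3), STAT2 from 647 ± 36.5 to 1482 ± 64.8 and OAS1 from 153 ± 21.6 to 519 ± 45. With an estimated correlation the calls for nuclear transport, ribosome biogenesis, ribosomal protein and interferon genes held (adjusted p = 0.0229, 0.00147, 0.0229 and 0.00704). KPT libraries were shallower than the other MAVER libraries, at 5374226 to 7924550 reads.

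Histone genes of the replication-dependent class rose in 11 of 14 cases and fell in 0, also when adjusted over the list alone (median log2 fold change 0.82, camera adjusted p = 0.0219, but adjusted p = 0.481 with an estimated correlation). HIST1H1C rose from 224 ± 20.1 to 351 ± 41.1 normalized counts and HIST1H4C from 5.33 ± 2.05 to 35 ± 10.6 (SD, n = 3). Most histone transcripts of this class lack poly(A) tails. Weighing carry-over of such RNA assumes a selection for poly(A) tails, which the protocol as given above does not state. The list's median stood at 0.83 and 1.35 above the DMSO mean (log2) in KPT replicates A and C, the libraries with RNA45S5 at 53819 and 66933. It stood at 0.44 in KPT replicate B, with RNA45S5 at 9092. The call was lost without KPT replicate C (adjusted p = 0.0953). With replicate B as the only KPT library the median was 0.44 (adjusted p = 0.262), in a fit whose spread comes from the other groups alone.

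The p53 target list was higher with KPT, with 12 of 25 up and 6 down, also when adjusted over the list alone (camera adjusted p = 0.0219, but adjusted p = 0.148 with an estimated correlation). DDB2, a DNA damage recognition protein, rose from 261 ± 12.1 to 937 ± 37.9 normalized counts (SD, n = 3) and TP53INP1 from 748 ± 8.78 to 2093 ± 70.3. The nuclease gene AEN fell from 1453 ± 57.3 to 562 ± 42.6 and C12orf5 (TIGAR, a glycolytic regulator) from 367 ± 13.6 to 120 ± 1.79. NF-kB targets gave 7 up and 13 down of 31, also when adjusted over the list alone (camera adjusted p = 0.231). NFKB2 fell by 0.75 and NFKBIE by 0.87 on the log2 scale (SE 0.05 and 0.08), whereas PIM2 rose from 1120 ± 47.3 to 2740 ± 40.6. With KPT 3035 genes rose and 3167 fell of 11099 (limma, adjusted p under 0.05), 303 and 151 by at least 2-fold. Libraries did not overlap for 60.4% of genes against 10% by chance. With KPT replicate B as the only KPT library, assumed to vary like the other groups, 4860 genes were called. Of 3 measured markers of T and NK cells, too few for the list test, 2 rose and 1 fell with KPT, also when adjusted over the list alone (median log2 fold change 0.69).

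**Figure D3:**
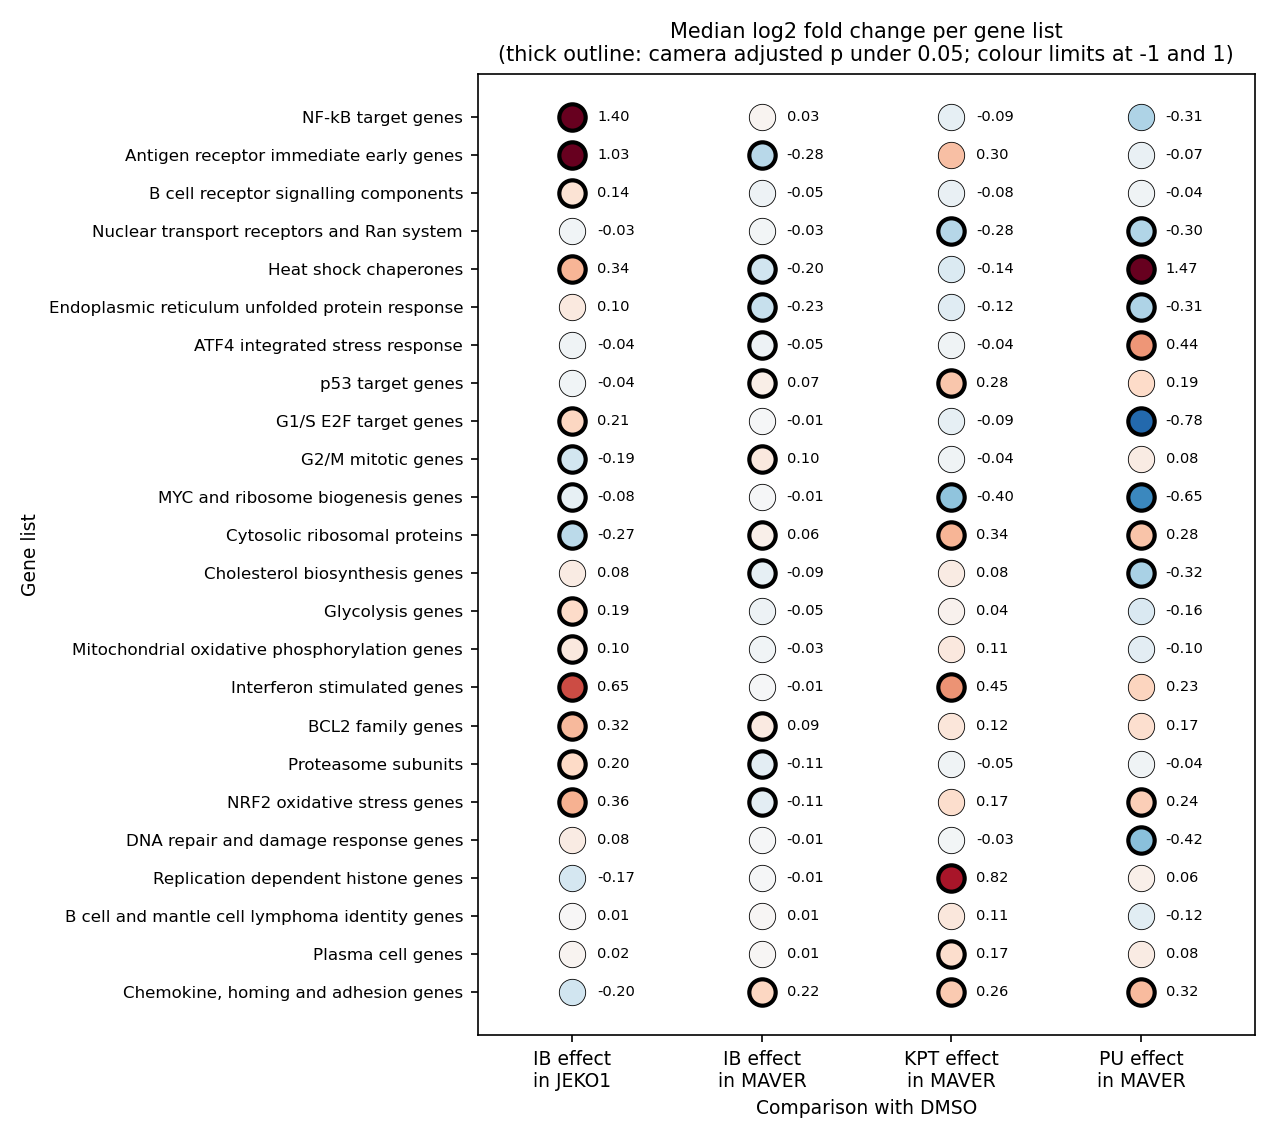
Median log2 fold change over DMSO of each gene list (vertical axis) in the 4 drug comparisons (horizontal axis), printed beside each circle; colour runs from -1 (blue) to 1 (red), and a thick outline marks a camera adjusted p under 0.05 at the preset correlation. NF-kB targets stand at 1.40 in the JEKO1 libraries labelled IB and 0.03 with IB in MAVER, and heat shock chaperones at 1.47 with PU.

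Set directly against IB in MAVER, KPT gave higher XPO1 (log2 difference 1.18 ± 0.04 SE, n = 3 per group, limma adjusted p = 1.34e-24), ARRDC3 (2.86 ± 0.06), PPDPF (2.60 ± 0.06) and CAPN5 (3.36 ± 0.27). It gave lower HK2 (-2.27 ± 0.06) and SH3TC1 (-1.54 ± 0.06). NFKBIA differed by -0.04 ± 0.06 (adjusted p = 0.579). The kinase gene PRKCB (-1.14 ± 0.04) and the apoptosis inhibitor BIRC3 (-1.08 ± 0.05) were lower with KPT than with IB. Interferon-stimulated genes were higher in 22 of 33 cases and lower in 3, also when adjusted over the list alone (camera adjusted p = 2.09e-06), with TRIM22 at 1.84 ± 0.05. Ribosomal proteins were higher in 48 of 51 cases and lower in 0 (49 and 0 adjusted over the list alone; camera adjusted p = 1.48e-13). NRF2 genes were higher in 13 of 22 cases and lower in 3, also when adjusted over the list alone (camera adjusted p = 0.00188). The ferritin gene FTL stood at 0.91 ± 0.04 and SLC7A11 at 1.06 ± 0.07.

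MYC-linked and ribosome biogenesis genes were lower with KPT than with IB in 28 of 39 cases and higher in 2 (29 and 2 adjusted over the list alone; camera adjusted p = 4.46e-10). Nuclear transport genes were lower in 23 of 33 cases and higher in 3, also when adjusted over the list alone (camera adjusted p = 1.33e-05). ODC1, the first enzyme of polyamine synthesis, was one of the 2 members of the MYC-linked and ribosome biogenesis list that were higher (0.94 ± 0.04, log2 difference ± SE). These 5 calls held with an estimated correlation (adjusted p = 0.00133 for ribosome biogenesis, 0.00471 for interferon and 0.0316 for each of the others). Immediate early genes were higher in 20 of 26 cases and lower in 2, also when adjusted over the list alone (camera adjusted p = 4.49e-07, but adjusted p = 0.0522 with an estimated correlation). DUSP1 stood at 1.89 ± 0.16, RGS2 at 1.32 ± 0.09 and PPP1R15A at 1.31 ± 0.08. Between the drugs 3002 genes were higher with KPT and 3127 lower of 11099 (limma, adjusted p under 0.05), and 4730 were called with replicate B as the only KPT library, assumed to vary like the other groups.

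PU, the treatment that the labels do not define, raised heat shock chaperones in MAVER. HSPA6, an inducible chaperone, rose from 13.2 ± 4.96 to 947 ± 9.94 normalized counts (SD, n = 3), HSPB1 from 1402 ± 33.3 to 16877 ± 671, DNAJB1 from 1926 ± 48.9 to 12187 ± 122 and HSP90AA1 from 21315 ± 565 to 130100 ± 4963. HSPA1B, whose reads may be shared with its near-identical copy HSPA1A, rose from 38 ± 8.49 to 1200 ± 199. Of 30 chaperones 25 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 6.35e-28). Outside this list, the growth factor gene PGF rose from 5.85 ± 2 to 219 ± 14.3 and LCN10 from 66.9 ± 10.6 to 1142 ± 21.8. P4HA2, a collagen prolyl hydroxylase, rose from 87.3 ± 5.51 to 1324 ± 32.2 and COL1A1 from 61.1 ± 2.19 to 680 ± 46.2. COL1A1 is one of 5 measured markers of epithelial, fibroblast or erythroid cells, of which 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0591, not called, but 0.0498 without DMSO replicate B). The 3 measured markers of T and NK cells, too few for the list test, all rose with PU, also when adjusted over the list alone (median log2 fold change 0.75). NFKBIA fell from 873 ± 25.1 to 522 ± 38 (log2 fold change -0.74 ± 0.06 SE, limma adjusted p = 6e-14). XPO1 fell from 5232 ± 99.2 to 4260 ± 191 (-0.30 ± 0.04, adjusted p = 8.93e-08) and BTK from 2839 ± 63.1 to 2467 ± 81.6 (-0.20 ± 0.04, adjusted p = 0.000106).

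Genes of the ATF4 stress response, which includes amino acid synthesis, rose with PU in 22 of 32 cases and fell in 6, also when adjusted over the list alone (camera adjusted p = 8.68e-07). The serine synthesis genes PHGDH and PSAT1 rose from 2280 ± 118 to 6678 ± 93.1 and from 836 ± 18.4 to 2647 ± 29.5 normalized counts (SD, n = 3), and DDIT4, an inhibitor of mTOR signalling, from 652 ± 12 to 2334 ± 17.6. NRF2 genes rose in 13 of 22 cases and fell in 5 (14 and 5 adjusted over the list alone; camera adjusted p = 0.00217). HMOX1, heme oxygenase, rose from 470 ± 20.2 to 2092 ± 55.4. Ribosomal proteins rose in 46 of 51 cases and fell in 0 (47 and 0 adjusted over the list alone; camera adjusted p = 3.18e-13), for example RPL3 by 0.42 ± 0.04 (log2 fold change ± SE). The unfolded protein response list was lower, with 18 of 28 down and 7 up (18 and 8 adjusted over the list alone; camera adjusted p = 0.000257, but adjusted p = 0.0801 with an estimated correlation). Among its members HSPA5, the chaperone of the endoplasmic reticulum, fell from 6274 ± 123 to 3406 ± 78.7, CALR from 10223 ± 112 to 5762 ± 64.1 and MANF from 648 ± 16.6 to 248 ± 15.1.

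Lists for the G1/S transition, ribosome biogenesis, DNA repair and lipid synthesis were lower with PU. Of 40 G1/S genes 39 fell and 0 rose (39 and 1 adjusted over the list alone; camera adjusted p = 9.38e-27). The replication helicase subunit MCM7 stood at 8384 ± 187 against 16328 ± 121 normalized counts with DMSO, the sliding clamp PCNA at 1882 ± 122 against 3795 ± 53.6 and UNG at 525 ± 27.9 against 1411 ± 44.5 (SD, n = 3). The cyclin E genes CCNE1 and CCNE2 fell by 1.67 and 1.75 on the log2 scale (SE 0.14 and 0.09). Of 40 mitotic genes 16 rose and 4 fell (15 and 4 adjusted over the list alone), with no call for the list (camera adjusted p = 0.0579). The list was called upward without DMSO replicate C (adjusted p = 0.0402), without PU replicate C (0.0316) and with upper-quartile scaling (0.0474). Of 39 MYC-linked and ribosome biogenesis genes 36 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 3.36e-20). NOLC1 (-0.88 ± 0.04) and ODC1 (-0.84 ± 0.04) were among those that fell. Of 35 DNA repair genes 26 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 9.32e-10). The mismatch repair gene MSH6 stood at -1.02 ± 0.05. Of 27 genes of cholesterol and lipid synthesis 20 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 1.24e-06). The fatty acid synthase FASN stood at -1.16 ± 0.06 and the desaturase SCD at -1.11 ± 0.04.

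Nuclear transport genes fell with PU in 24 of 33 cases and rose in 4 (24 and 5 adjusted over the list alone; camera adjusted p = 4.27e-05). XPO5 and IPO4 each fell by 0.82 on the log2 scale (SE 0.05), while RANGAP1 rose from 3461 ± 210 to 6936 ± 248 normalized counts (SD, n = 3). Apart from the unfolded protein response, the PU list calls given here held with an estimated correlation, with adjusted p = 0.000329 for chaperones, 0.00179 for ATF4, 3.04e-05 for G1/S, 4.85e-05 for ribosome biogenesis, 0.00164 for DNA repair and 0.00453 for cholesterol and lipid synthesis. It was 0.0226 for each of nuclear transport, ribosomal protein and NRF2 genes. NF-kB targets gave 8 up and 15 down of 31 (8 and 16 adjusted over the list alone; camera adjusted p = 0.159). CFLAR, an inhibitor of caspase-8, rose from 656 ± 26 to 1496 ± 19.7, while BIRC3 fell from 1849 ± 51.9 to 1058 ± 83.6 and JUNB from 529 ± 45.3 to 205 ± 14.1. With PU 3066 genes rose and 3055 fell of 11099 (limma, adjusted p under 0.05), 357 and 138 by at least 2-fold. Libraries did not overlap for 61.2% of genes against 10% by chance.

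**Figure D4:**
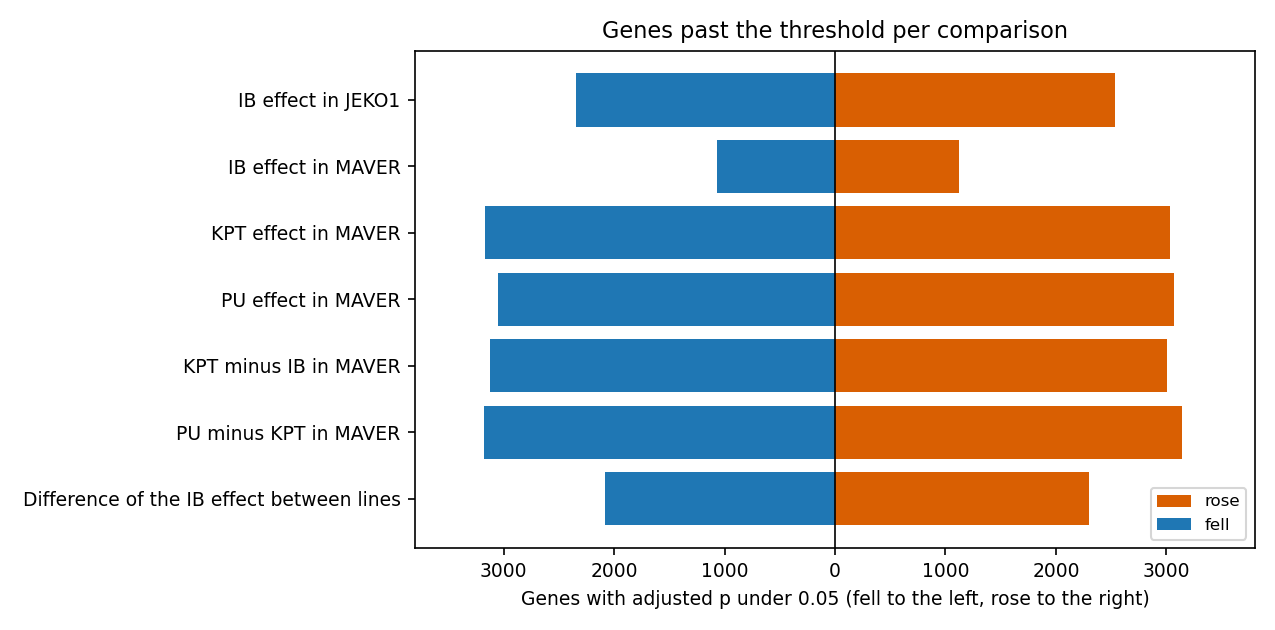
Number of genes with an adjusted p under 0.05 (limma) in each comparison, with genes that rose to the right of 0 and genes that fell to the left; in the bottom bar, right means a higher IB effect in JEKO1 than in MAVER. KPT has 3035 and 3167 genes, PU 3066 and 3055, and IB in MAVER has 1126 and 1071.

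PU was also set directly against KPT. HSPA6 was higher with PU than with KPT (log2 difference 6.10 ± 0.24 SE, n = 3 per group), as were SERPINH1, the collagen chaperone (3.29 ± 0.14), and COL1A1 (3.79 ± 0.14). XPO1 was lower (-1.40 ± 0.04, limma adjusted p = 6.2e-28), as were NFKBIA (-0.65 ± 0.06, adjusted p = 2.83e-12), ARRDC3 (-2.80 ± 0.06), DDB2 (-2.26 ± 0.08) and CCNE2 (-2.06 ± 0.09). Chaperones were higher with PU in 27 of 30 cases and lower in 1, also when adjusted over the list alone (camera adjusted p = 4.94e-31). ATF4 genes were higher in 22 of 32 cases and lower in 5, also when adjusted over the list alone (camera adjusted p = 1.07e-06), with WARS, a tRNA synthetase, at 1.78 ± 0.04 and PSAT1 at 1.68 ± 0.05.

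G1/S genes were lower with PU than with KPT in 38 of 40 cases and higher in 1, also when adjusted over the list alone (camera adjusted p = 2.59e-23), with E2F1 at -1.45 ± 0.05 (log2 difference ± SE). DNA repair genes were lower in 28 of 35 cases and higher in 3. So were cholesterol and lipid synthesis genes in 21 of 27 and higher in 1, and interferon-stimulated genes in 21 of 33 and higher in 3, each the same adjusted over the list alone (camera adjusted p = 5.2e-08, 5.2e-08 and 0.00334). TRIM22 (-1.42 ± 0.05) and HERC5 (-1.58 ± 0.10) were lower, while BST2 was higher (2.01 ± 0.06). These 6 calls held with an estimated correlation (adjusted p = 0.000334 for chaperones, 5.21e-05 for G1/S, 0.0194 for interferon and 0.00248 for each of the others). Ribosomal proteins gave 14 of 51 lower and 2 higher (9 and 2 adjusted over the list alone), with no call for the list (camera adjusted p = 0.149). MYC-linked and ribosome biogenesis genes were lower with PU in 19 of 39 cases and higher in 6, also when adjusted over the list alone. That list was called downward (camera adjusted p = 0.00377, and 0.0194 with an estimated correlation). Nuclear transport genes gave 15 of 33 lower and 11 higher, also when adjusted over the list alone, with no call (camera adjusted p = 0.966). In all, 3145 genes were higher with PU and 3178 lower of 11099 (limma, adjusted p under 0.05), and 4993 were called with replicate B as the only KPT library, assumed to vary like the other groups.

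The 3 MAVER drug comparisons share their DMSO libraries, so their changes correlate by chance. IB and KPT had 685 genes that rose with both (independent lists would share 308) and 558 that fell with both (306), TP53INP1 among the former. Another 144 rose with IB and fell with KPT (321) and 169 did the reverse (293). IB and PU shared 653 rises (311) and 460 falls (295), WNT10A among the latter, while 153 rose with IB and fell with PU (310) and 244 did the reverse (296). KPT and PU shared 1576 rises (838) and 1616 falls (872), HK2 and NOLC1 among the latter, with 337 and 442 genes moving opposite ways (835 and 875). In 20 simulations with all groups, controls included, drawn from the DMSO means, at most 1 gene was shared. Hardly any gene can be called where none changes, so that count is no measure for the overlaps above. The correlation of log2 fold changes across genes was 0.38 for IB and KPT, 0.244 for IB and PU and 0.43 for KPT and PU, against 0.434, 0.482 and 0.447 in the simulations. The simulated fold changes hold only noise and shared controls, without any drug effect. Their correlations are therefore no reference for the observed ones, and a lower observed value does not show that the drugs share less. Covariances were 0.0528, 0.0353 and 0.0975 against simulated 0.00891, 0.00886 and 0.00882, differences of 0.0439, 0.0264 and 0.0887. The 3 controls were not split between the comparisons, so part of each overlap may come from the shared controls.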

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

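The differences between lines were planned, and the tests that weigh explanations for them, with those on exchanged JEKO1 labels, were chosen only after the result was seen. The IB effect differed between JEKO1 and MAVER for 4385 genes, and 1260 genes called in both lines moved opposite ways and 155 the same way. With the JEKO1 labels exchanged 2424 genes would differ, 1629 of them among the 4385, and 1260 genes would move the same way and 155 opposite ways. In median difference of log2 fold change (JEKO1 minus MAVER), the lists that differed were NF-kB targets (1.38), immediate early genes (1.3) and heat shock chaperones (0.54). Others were interferon-stimulated genes (0.65, adjusted p = 0.0649 with an estimated correlation), NRF2 genes (0.42), proteasome subunits (0.34) and G1/S genes (0.23). Ribosomal proteins stood at -0.33. The unfolded protein response (0.33), glycolysis (0.20), oxidative phosphorylation (0.18) and mitotic genes (-0.29) also differed, but not with an estimated correlation (adjusted p = 0.13, 0.447, 0.163 and 0.143). The glycolysis call was also lost without JEKO1 IB replicate A (adjusted p = 0.124) or MAVER IB replicate C (0.0527). With the JEKO1 labels exchanged, the camera calls would be NF-kB targets (-1.10), interferon-stimulated genes (-0.66), NRF2 genes (-0.24), G1/S genes (-0.18), BCL2 family genes (-0.38) and ribosomal proteins (0.21). Immediate early genes (-0.56), heat shock chaperones (-0.15), proteasome subunits (-0.11) and ribosome biogenesis genes (0.13) would also be called, but not with an estimated correlation (adjusted p = 0.0502, 0.232, 0.249 and 0.0502).

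The differences per gene hold for the labels as given. Among signalling and NF-kB genes the difference was 1.65 for NFKBIA, 3.00 for CD83, 2.19 for NFKB2, 2.37 for JUNB, 2.88 for NR4A1, 3.79 for NR4A3 and 4.56 for PTPN6. It was 0.44 for BTK and 0.20 for XPO1. Other genes higher in JEKO1 were WNT10A (5.40), CYTH4 (4.51), MPEG1 (3.79), CD72 (3.35), SPIB (1.90), SLC7A11 (1.86), HSPH1 (1.18), HSP90AA1 (0.97), SQSTM1 (0.76) and PSMD1 (0.52). Genes lower in JEKO1 were RAG1 (-5.39), TMCC2 (-4.18), FBP1 (-3.72), C10orf10 (-3.47), S1PR4 (-2.26), BACH2 (-1.72), POU2AF1 (-1.71), CXCR4 (-1.14), CDC25B (-1.05), MYC (-0.87) and RPL22 (-0.71).

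The pattern weighed is that 89% of the genes called in both lines changed in opposite directions with IB, with NF-kB targets and PTPN6 higher in the JEKO1 libraries labelled IB. A single JEKO1 library with the wrong label is argued against, since the lowest correlation within JEKO1 groups exceeded the highest between groups by 0.0171. The RNA45S5-rich library JEKO1 DMSO replicate C is argued against as the source, since 90.8% of genes called in both lines moved opposite ways without it. An exchange of the DMSO and IB labels of JEKO1 as a whole and an opposite response of the lines to the same drug both predict the 89%, so with 1 DMSO and 1 IB group per line they cannot be told apart here. The difference between the lines as biology was not tested further, and every JEKO1 direction in the text may therefore be inverted.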

How the results depend on the processing

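Results without the RNA45S5-rich KPT libraries, with thinned reads, the exchanged JEKO1 labels, and the left-out replicates and upper-quartile scaling of the list tests were chosen only after the result was seen. All other settings were planned. The count of called genes stayed within 1.5 times its value under each setting run, for all 7 comparisons, except that with the JEKO1 labels exchanged the difference between lines called 2424 genes instead of 4385. Leaving out 1 replicate at a time gave 4175 to 4587 genes for IB in JEKO1, 1694 to 2033 for IB in MAVER, 5679 to 5811 for KPT, 5582 to 5710 for PU. It gave 5627 to 5817 for KPT against IB, 5828 to 5943 for PU against KPT and 4053 to 4279 for the difference between lines. edgeR on recovered reads called, in this order, 4923, 2347, 6171, 6425, 5947, 6273 and 4420 genes. DESeq2, which was not run on the difference between lines, called 4076, 1896, 5601, 5816, 5436 and 5745. Thinned reads gave 1767 genes for IB in MAVER, 5507 for KPT and 5477 for PU, against 2197, 6202 and 6121 at full depth, so lower depth gave fewer calls. Scaling to equal totals moved the share of higher calls the furthest for PU, from 50.1% to 43.7%. There 2675 genes rose and 3443 fell, instead of 3066 and 3055, so the even balance with PU depends on the scaling. Of 257 named results, 252 were called. Of their values under other settings, 4631 of 4644 kept direction and call, 13 lost the call (XPO1 and BTK, which have small changes) and 0 reversed. Apart from BTK, XPO1 and NFKBIA, the named genes were picked for large changes or small p in these same data. Most were therefore bound to keep their call, and these counts do not measure how stable other genes are. With a filter at a mean of 100, which tests fewer genes, 229 of the named results were called, and without the variance trend 249; the cause of the latter was not tested.

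List tests depend more on the method. At the preset correlation 78 of 175 tests were called. Only 38 were called with a correlation estimated from the libraries, which is a stricter test. It could give a larger p even where the estimated correlation lay below the preset 0.01. For interferon-stimulated genes with IB in JEKO1 that correlation was -0.018, and the camera p was 0.016 instead of 0.000398. A lost call therefore does not by itself show that the members of a list vary together. The directional fry test, which asks whether a list moves one way without comparing it with other genes, called 144, and the mixed fry test, which counts change in either direction, called 170. In 2 cases the directional fry test made a call in the opposite direction to camera, which made none. For plasma cell genes with IB in JEKO1 (median 0.024) camera pointed downward and fry upward (fry adjusted p = 0.0138). For glycolysis genes with KPT (median 0.041) camera pointed upward and fry downward (fry adjusted p = 0.0313). The cause was not tested. Total-sum scaling gave 79 calls, and pseudocount 8 also 79. At the smallest simulated fold the limma test recovered 24 of 49 genes (49%) for IB in JEKO1, 33 of 50 (66%) for IB in MAVER and 27 of 49 (55.1%) for KPT. Each share rests on a single draw of few genes, so their order is not interpreted.

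With the replicate letter as a block (replicate block), 5507, 2155, 6170, 6093, 6089, 6300 and 4728 genes were called in the same order of comparisons, and 80 list tests. The letters share only a name. Deviations of same-lettered libraries correlated at -0.036 to 0.118 in JEKO1, 1 of 3 pairs over 0.1, and at -0.092 to 0.104 in MAVER, 1 of 18 pairs over 0.1. With the block, glycolysis genes with PU (adjusted p = 0.0471 instead of 0.0502) and ribosome biogenesis genes in the difference between lines (0.0467 instead of 0.056) were called. Both lie near the threshold: the first were also called with total-sum (0.032) and upper-quartile scaling (0.049) and when 4 of the replicates were left out singly (0.0252 to 0.0498), the second when 5 were (0.0314 to 0.0486).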

Other observations

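The first 2 paragraphs hold planned tests, except the glycolysis test without IB replicate A. That test, the tests that weigh explanations and the splits of the samples were chosen only after the result was seen. BCL2 family genes, which govern apoptosis, rose in 7 of 16 cases with IB in MAVER and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.00404, but adjusted p = 0.0696 with an estimated correlation). BCL2 rose from 10607 ± 173 to 14563 ± 405 normalized counts (SD, n = 3), the pro-apoptotic BMF from 174 ± 5.71 to 289 ± 13.6 and HRK from 21.7 ± 0.992 to 67.7 ± 9.22. In the JEKO1 libraries labelled IB, 11 of 16 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.0268, but adjusted p = 0.141 with an estimated correlation). BID rose from 448 ± 15.8 to 826 ± 27.5 and HRK fell from 111 ± 11.1 to 29.2 ± 7.56. With KPT 7 of 16 rose and 3 fell, also when adjusted over the list alone, with no call for the list (camera adjusted p = 0.179). BMF rose to 466 ± 48.1, BBC3 from 40 ± 7.27 to 114 ± 5.35 and PMAIP1 from 1716 ± 61.4 to 2495 ± 101. Glycolysis genes of JEKO1 rose in 15 of 29 cases and fell in 4 (15 and 6 adjusted over the list alone; camera adjusted p = 0.0223, but adjusted p = 0.574 with an estimated correlation, and 0.124 without IB replicate A). VEGFA, a hypoxia target on this list, rose from 132 ± 13.3 to 337 ± 35.8, and ALDOC fell from 675 ± 28.3 to 237 ± 40.4.

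Chemokine, homing and adhesion genes rose in 7 of 20 cases with IB in MAVER and fell in 4 (9 and 4 adjusted over the list alone; camera adjusted p = 0.00422, but adjusted p = 0.0983 with an estimated correlation). With KPT 13 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.0119, but adjusted p = 0.148 with an estimated correlation). With PU 11 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.00219, but adjusted p = 0.0746 with an estimated correlation). S1PR4, a receptor of lymphocyte egress signals, stood at 408 ± 26 normalized counts with DMSO, 1010 ± 80.1 with IB and 941 ± 23.4 with KPT, and the chemokine receptor CXCR4 at 8948 ± 144, 12109 ± 573 and 13247 ± 433 (SD, n = 3). In JEKO1 this list gave 5 of 21 up and 10 down, also when adjusted over the list alone, with a median of -0.20, a mean of 0.19 and no call (camera adjusted p = 0.261). CXCR4 fell from 11653 ± 124 to 7137 ± 116 and CXCR5 rose from 122 ± 8.27 to 290 ± 10.4. Plasma cell genes rose with KPT in 9 of 16 cases and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.0216, but adjusted p = 0.148 with an estimated correlation). TNFRSF17, the receptor BCMA, rose from 526 ± 16.4 to 1488 ± 31. With IB, CD38 rose from 570 ± 39.6 to 1105 ± 38.2 and IGJ (JCHAIN) from 4601 ± 180 to 7128 ± 259, without a call for the list (camera adjusted p = 0.196). The B cell identity list was called in none of the 4 drug comparisons with camera (adjusted p = 0.84, 0.935, 0.342 and 0.235). CCND1, the cyclin that marks this lymphoma, fell with PU from 57958 ± 956 to 42986 ± 1237. Markers of T and NK cells gave 2 of 5 up in JEKO1 (camera adjusted p = 0.142). In MAVER 3 were measured, of which 3 rose with PU (median 0.75) and 2 rose and 1 fell with KPT (median 0.69), while with IB the median was 0.15 and none was called. Of 3 measured myeloid markers 1 rose in JEKO1 and 2 fell with IB in MAVER, and none was called with KPT or PU. Lists of 3 are too few for the list test.

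Higher histone transcripts with KPT were weighed against carry-over of RNA without a poly(A) tail and against depth, and reads thinned to 1 depth left a median of 0.759 (adjusted p = 0.0443, close to the threshold), which argues against depth as the whole cause, although 7 of 14 genes rose instead of 11. With the RNA45S5 level as a covariate the median log2 fold change of the list was 0.565 (member SD 0.603) instead of 0.824 (0.583), 7 of 14 genes rose instead of 11, and the list test lost its call (adjusted p = 0.095). The covariate also took the calls over all genes from 6202 to 5842, and the cause of the lost call was not tested. Against carry-over as the whole cause stand only single libraries. JEKO1 DMSO replicate C had RNA45S5 at 65331 and a list median of 0.07 over the DMSO mean. PU replicate A had 32274 and 0.21, with HIST1H4C at -0.84. KPT replicate B had 9092 and 0.44, with HIST1H4C at 2.08. The JEKO1 DMSO mean includes replicate C itself, which makes its values smaller. Replicates A and B had list medians of -0.06 each. HIST1H4C stood at 1.05 in replicate C against -0.4 and -0.65 in A and B, which goes with carry-over. Carry-over may account for part of the rise, and it cannot be told apart from an effect of the drug, since KPT replicates A and C had the highest RNA45S5 of the MAVER libraries.

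Higher ribosomal protein transcripts with KPT, at a median log2 fold change of 0.337, were weighed against transcript length, abundance and depth. Of 10000 random lists matched on length and mean, the highest median was 0.253. Length was that of the longest annotated transcript, found for 51 of 51 members, with a median of 1962 bases. That transcript may not be the one expressed, and how closely the genes matched was not checked. The draws argue against length and abundance only as measured in this way, and short expressed transcripts stay open as a cause. Thinned reads left a median of 0.326 (adjusted p = 7.24e-21), which argues against depth. Reads shared with ribosomal protein pseudogenes were not tested and stay open, as does a drug effect, so a response of ribosomal protein transcripts to KPT is a hypothesis.

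Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05; 1 of the 10, the real split, gave as many genes in each comparison. The real and the highest other counts were 4879 and 0 for IB in JEKO1, 2197 and 0 for IB in MAVER, 6202 and 0 for KPT, 6121 and 0 for PU, 6129 and 0 for KPT against IB, and 6323 and 1 for PU against KPT. For the difference between lines 100 of 200 splits were drawn, and 1, the real one with 4385 genes, reached that count. These splits mix the labels of both lines, so an IB effect in either line sets the real one apart, and they do not test a difference between lines. Of the drawn splits 7 kept the JEKO1 labels, the real one included, with a highest other count of 2438, too few for a share under 0.05. The others gave at most 141.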
